A study of Vachellia cornigera with 24 samples.

How the data were processed

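Extrafloral nectaries of Acacia cornigera were sampled in the field, pooled over plants for each biological replicate, and sequenced as 24 barcoded paired-end libraries, per the labels' protocols. The deposited table holds normalised counts, a score with no fixed unit, which the authors scaled between libraries and rounded to whole numbers; the method of scaling, the aligner, the assembly and the annotation are not given in the sources used here. Per the file headers, each of the 12650 genes carries the closest Arabidopsis thaliana locus, each listed once, and a description. These include 37 plastid and 27 mitochondrial loci. No genome was used, so positions are not given. The table also holds the authors' mean for each of the 10 groups, which was not used. For the groups of 3 libraries these means lie within 4.67 of the means of the printed values, and for 3 am and gut contents, with 2 libraries each, they differ by up to 40 and 45.

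Since the values are not raw counts, they were tested on the scale log2(value + 1), on which the change of low genes is understated. Genes with a mean of at least 10 over all libraries were tested (12264 tested, 386 left out). All 24 libraries entered 1 linear model with a coefficient for each of the 10 groups (limma 3.58.1 with a mean-variance trend, R 4.3.3, 14 residual and 3.657 prior degrees of freedom), so that all groups share an estimate of the spread. The 2 pm library and the library with returned ants have no replicate and add nothing to the spread. Replicates at 9 am and 3 pm varied more than those of the other groups. The shared estimate is thus likely too small for comparisons with these groups, and their p-values too low. For comparisons without these groups it is likely too large and their p-values too high, if the replicates are independent. A missed call there is weak evidence of no change. Tests were 2-sided and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, at a threshold of 0.05. A moderated F test compared 9 am, noon, 3 pm, 3 am and 8 am, and 9 comparisons of 2 groups were fixed before the data were examined. A further comparison, noon against the 8 am controls, was added after the data were seen because the 9 am libraries differ among themselves.

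Before the data were examined, 18 gene lists with 333 Arabidopsis loci were fixed, of which 250 are in the table. They cover morning-phased and afternoon- and evening-phased clock genes, starch breakdown, starch synthesis, sucrose synthesis and sugar export, nectary development, photosynthesis, jasmonate, salicylate and pathogen response, heat shock, endoplasmic reticulum folding, phenylpropanoids and flavonoids, abscisic acid and drought, cell cycle, and markers of phloem, xylem, guard cells and cuticle as other cell types. Lists were tested with camera in limma at a preset correlation of 0.01, with adjustment over the 162 tests of 18 lists in 9 comparisons, and again with an estimated correlation, under which 0 of the 55 calls held. CCA1, PRR9, SPS2F, CRC, MYB21, JAZ10 and LHCB1.3 are not in the table and were not analysed here.

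The genes named were chosen by a rule fixed before the data were examined: up to 10 rises and 10 falls per comparison among called genes whose groups do not overlap, 1 per gene name, up to 4 called members of each list with the smallest adjusted p, the 20 genes with the smallest p in the F test, and a fixed set of nectary, clock and defence genes. The wording of the rule allows more than 1 reading. The reading used reduces genes to 1 per name first and ranks them afterwards, and it was settled after a first listing had been seen. Of 140 genes it takes as largest changes, 43 differ from those of the other reading; no test depends on it.

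The pairing of libraries by their sample numbers was checked by the correlation of deviations from the group means across genes. Libraries correlated best with the one of their own number in 6 of 6 cases for 8 am against 9 am (0.16 to 0.42) and in 4 of 6 for Gracilis against removal of the ants (0.22 to 0.51), the 2 comparisons where equal numbers went together by the rule used; the labels give no reason for a pairing, and the planned fit has no block.

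Replicates were also compared with the noise that counting would give. Noon samples 1 and 3, and samples 2 and 3 without ants, differed least. Where a noise index of 1 stands for counting noise at 1 read per unit, these pairs had an index of 1.90 to 1.96 for genes with means of 20 to 200, 2.04 to 2.30 from 200 to 2000, 2.95 to 3.60 from 2000 to 20000 and 13.0 to 18.5 above that. The 18 other pairs of replicates had 3.02 to 25.3, 4.22 to 83.0, 11.5 to 420 and 191 to 14075. How many units a read is worth is unknown, so these values do not settle whether the pairs are separate biological samples. They were kept as separate libraries as planned, and the F test, the comparisons of 2 groups in the report, noon against 8 am, gut contents against removal of the ants and the number of list calls were recomputed with each pair taken as 1 library, an alternative chosen after the data were seen.

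The tests were run first on simulated data for 12264 genes with 100 genes changed at each size. Noise was normal and independent between genes and libraries, with the same SD for a gene in all groups. A log2 change of 1 was recovered in 41% of changed genes for noon against 9 am, 31% for 3 am against 3 pm and 57% for removal of the ants, and a log2 change of 3 in 94%, 93% and 96%. False calls were 10 of 145, 4 of 128 and 10 of 163. The simulation lacks the wider spread at 9 am and 3 pm, the near-identical pairs described above and correlation between genes. These rates therefore need not hold for the real libraries. The table gives no raw depth, so no counting interval is given; the precision of each value is given by the spread of its replicates.

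The alternatives were pseudocounts of 0.1 and 10, no filter and a filter 5 times as high, median-of-ratios and quantile scaling, a fit of the compared groups alone, array quality weights, a replicate block, a 2-fold threshold, other choices of control group, and leaving out each library in turn. Added after the data were seen were the near-identical pairs as 1 library, a fit without 9 am and 3 pm, leaving out sample 1 of each ant treatment, the block in the compared groups alone, and median-of-ratios scaling of the 2 pm library and the library with returned ants against the 8 am controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.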

Results

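RNA was sequenced from extrafloral nectaries, the sugar-secreting glands outside the flower, of the bullhorn acacia (Acacia cornigera), a tree that houses and feeds ants of the species Pseudomyrmex ferrugineus. The 24 libraries came from plants in the field. A time course held 3 libraries at 9 am, 3 at noon, 1 at 2 pm, 3 at 3 pm, 2 at 3 am of the second day and 3 at 8 am, which served as controls for the ant treatments. In the ant treatments, 3 libraries came from plants kept without ants for 2 days and 3 from a treatment titled Gracilis replacement (Gracilis below). A treatment titled gut contents applied (gut contents below) had 2 libraries. The last, with 1 library, was titled ants replaced after 2 days (returned ants below). The labels give a clock time for the returned ants (9 am) but not for the other ant treatments, and they do not say whose gut contents were used. Each library pooled nectaries of different plants. The table lists 12650 genes by their closest Arabidopsis locus, and 12264 of them entered the tests. Normalised counts per library, rounded, summed to 21084300 to 23895100 at 9 am, 21502700 to 23560800 at noon, 22024100 to 25679900 at 3 pm, 23648400 and 23715700 at 3 am and 24515200 to 26982100 at 8 am. They summed to 26015400 to 27077100 without ants, 25594700 to 25930100 for Gracilis, 26575700 and 27582100 for gut contents, 32520500 in the 2 pm library and 27507800 in the library with returned ants. Values below are means of normalised counts ± SD over these libraries.

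In every 9 am and 3 pm library the values lay closer to a library of another group than to the rest of its own group. The same held in 6 of the 16 other libraries with replicates (3 am sample 1, sample 1 without ants, Gracilis samples 1 and 3 and both gut contents samples). The 9 am libraries correlated with each other, across genes on the log2 scale, at 0.915, while 9 am sample 3 correlated with 3 am sample 1 at 0.971. The transcript of LHY, a transcription factor of the circadian clock that peaks around dawn in Arabidopsis, stood at 20730, 2525 and 83100 in the 3 libraries labelled 9 am. At noon 2 of the 3 libraries (samples 1 and 3), and among those without ants samples 2 and 3, differed less from each other than any other replicates did. The protocols describe each replicate as a pool of different plants, but the values leave open whether these pairs are separate biological samples. Counts with each pair taken as 1 library stand beside the results they change.

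**Figure D1:**
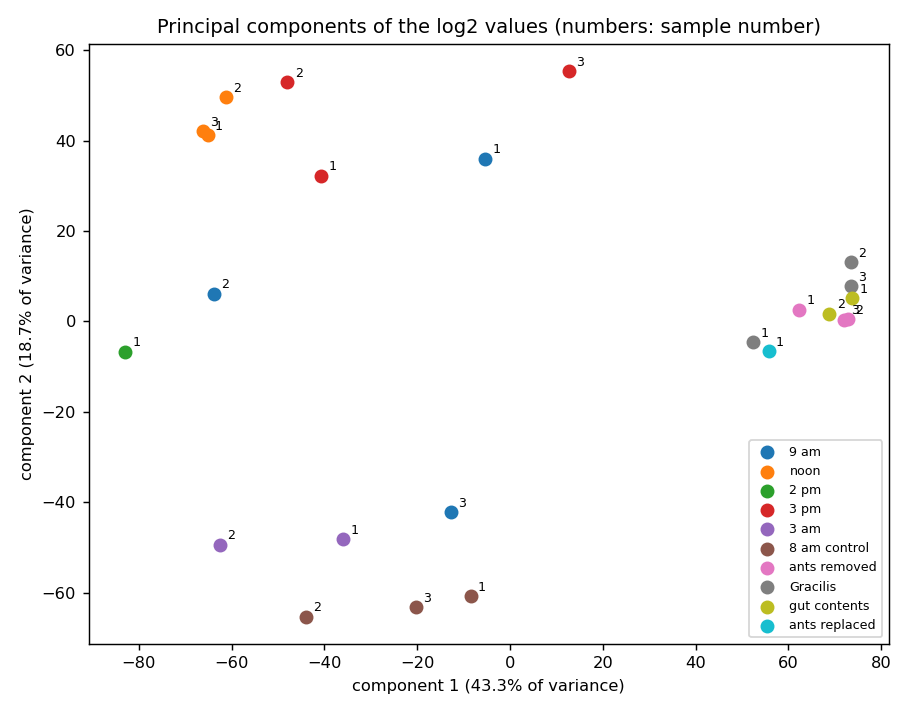
Principal components of the log2 values of all 24 libraries; each point is a library, colours are groups and numbers are sample numbers. Component 1 (43.3% of the variance) separates the ant treatments from the time course, and the 9 am and 3 pm libraries are scattered.

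The first question was which genes differ between times of day in untreated nectaries. The 3 am libraries are titled day 2, and the 8 am libraries are the controls of the ant treatments. For these groups, here and in the comparisons below, time of day cannot be told apart from sampling day or series. SWEET9, the sugar transporter that exports sucrose in nectaries of other plants, averaged 174589 ± 43459 at 8 am (n = 3), 84472 ± 64261 at 3 am (n = 2) and 2450 ± 96.8 at noon (n = 3). AT3G22840, a gene of the chlorophyll A-B binding family, averaged 20917 ± 3484 at 8 am and 208 ± 32.7 at noon. AT5G01600, a ferritin that stores iron, ran the other way with 4363 ± 752 at 8 am and 15975 ± 463 at 3 pm, and AT1G48850, chorismate synthase of the shikimate pathway, averaged 7648 ± 163 at 8 am and 2647 ± 326 at 3 pm. The F test over the 5 replicated times (limma, 14 libraries) called 4865 of 12264 genes (39.7%), and with each near-identical pair as 1 library it called 3200. It called 2678 without the 8 am group, 2985 in a fit of these groups alone, 3167 at a change of at least 2-fold and 7315 with array quality weights. Of the called genes 1661 had their highest mean at 8 am, 1347 at noon, 1074 at 3 pm, 720 at 3 am and 63 at 9 am. The 9 am mean averages unlike libraries, which can keep it from being the highest. The 63 therefore does not show that few genes peak at 9 am. Among the smallest adjusted p were 3.85e-07 for AT3G55880, an alpha/beta hydrolase, and 4.71e-06 for AT3G22840.

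Of the gene lists fixed before the data were examined, photosynthesis had 25 of 33 members called by the F test (25 adjusted over the list alone), xylem and secondary wall 10 of 12 (10 adjusted over the list alone) and heat shock 10 of 14 (11 adjusted over the list alone). The test called 3 of 7 morning-phased clock genes (3 adjusted over the list alone) and 7 of 9 afternoon- and evening-phased ones (7 adjusted over the list alone). For sucrose synthesis and sugar export it called 13 of 19 members (14 adjusted over the list alone), for starch breakdown 10 of 19 (11 adjusted over the list alone) and for starch synthesis 8 of 16 (8 adjusted over the list alone). Phenylpropanoid and flavonoid genes had 15 of 21 called (18 adjusted over the list alone), jasmonate genes 7 of 16 (7 adjusted over the list alone) and salicylate and pathogen response genes 8 of 23 (8 adjusted over the list alone). Cell cycle genes had 8 of 18 called (9 adjusted over the list alone), endoplasmic reticulum folding genes 4 of 9 (4 adjusted over the list alone), nectary development genes 2 of 4 (2 adjusted over the list alone) and abscisic acid and drought genes 2 of 7 (2 adjusted over the list alone). Among markers of other cell types, guard cell genes had 4 of 5 called (4 adjusted over the list alone) and cuticle and epidermis genes 3 of 8 (5 adjusted over the list alone). Of the 5 phloem genes limma called 0 (0 adjusted over the list alone), with 0 at an unadjusted p under 0.05.

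**Figure D2:**
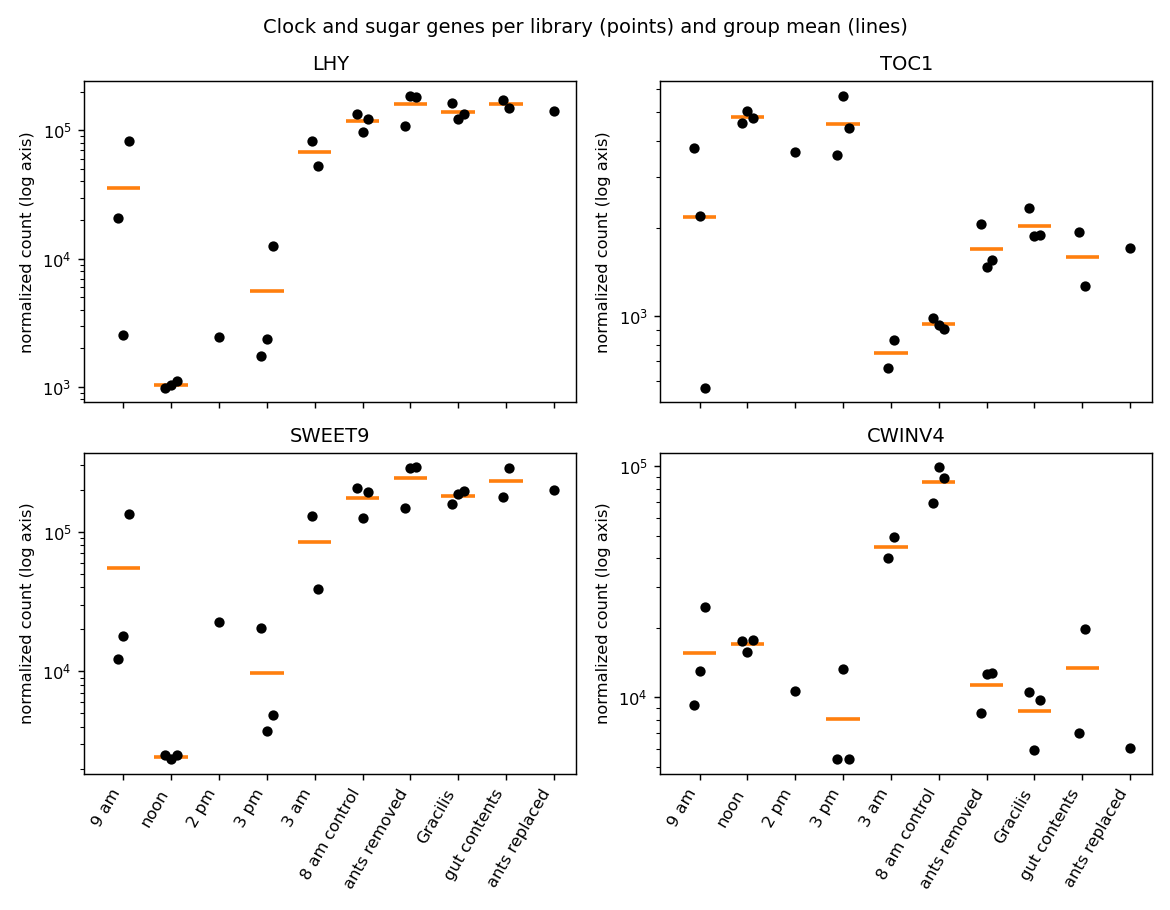
Normalised counts (log axis) of the clock genes LHY and TOC1, the sucrose transporter SWEET9 and the cell wall invertase CWINV4 in each library (points) with group means (lines) for groups with more than 1 library. The 3 points at 9 am span most of the range of the time course for LHY, and CWINV4 is highest at 8 am, with a mean of 85673.

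The comparison of noon with 9 am asked how nectaries changed over the morning. Of 33 photosynthesis genes 13 fell and 0 rose (19 fell adjusted over the list alone). LHCA4, an antenna protein of photosystem I, fell to 107 ± 14 from 6303 ± 5239 (log2 fold change -5.22 ± 0.88 SE, adjusted p = 0.00329), and LHCB5, an antenna protein of photosystem II, fell to 399 ± 35.2 from 8491 ± 6024. Heat shock genes fell in 8 of 14 cases (10 adjusted over the list alone). HSFA2, a heat shock transcription factor, stood at 62.7 ± 7.37 against 6015 ± 7880. LHY fell by 3.97 on the log2 scale (SE 0.84, adjusted p = 0.0121), among 3 of 7 morning clock genes that fell (3 adjusted over the list alone). TOC1, an evening repressor of the clock, rose to 4806 ± 233 from 2182 ± 1602 with ELF3 and ELF4, while PRR5 fell to 869 ± 123 from 5713 ± 3463, so that 3 of 9 evening clock genes rose and 1 fell (3 and 2 adjusted over the list alone).

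SWEET9 fell to 2450 ± 96.8 at noon from 55009 ± 69275 at 9 am (log2 fold change -3.66 ± 0.72, adjusted p = 0.00887). The sucrose list had 2 members up, among them the hexose transporter STP1, and 1 down (4 up and 3 down adjusted over the list alone), a split that turned to 0 up and 3 down under median-of-ratios scaling. Starch synthesis genes fell in 5 of 16 cases and none rose (5 down and 1 up adjusted over the list alone), with APS1, the small subunit of ADP-glucose pyrophosphorylase, at 494 ± 19.3 against 1203 ± 674. AMY3, an alpha-amylase, was among the 2 of 19 starch breakdown genes that rose (3 adjusted over the list alone). The jasmonate repressors JAZ1, JAZ2 and JAZ8 were among 4 of 16 jasmonate genes that fell (4 adjusted over the list alone). CCR1 and PAL2, which make lignin precursors, were among 3 of 21 phenylpropanoid genes that rose (4 adjusted over the list alone). LAC4, a laccase, was the 1 of 12 xylem genes that rose (4423 ± 178 against 1648 ± 832; 4 rose adjusted over the list alone). Of 5 guard cell genes KAT1 and HT1 rose while GC1 fell (3 up and 1 down adjusted over the list alone). The xylem list had a median log2 change of 1.25 and the phloem list, with no member past the threshold, one of 0.52. Of the remaining lists 2 of 4 nectary development genes (3 adjusted over the list alone), 2 of 23 salicylate genes (2 adjusted over the list alone) and 1 of 8 cuticle genes (1 adjusted over the list alone) rose. Of 9 endoplasmic reticulum genes 1 fell (2 adjusted over the list alone), and no cell cycle or drought gene passed. The invertase CWINV4 averaged 17032 ± 1126 against 15603 ± 7961 (adjusted p = 0.698), the sucrose-phosphate synthase SPS1F 3881 ± 124 against 6102 ± 1475 (adjusted p = 0.0542) and the clock gene GI 10562 ± 1750 against 11433 ± 9663 (adjusted p = 0.849).

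Genes with the largest rises at noon included AT1G23420, a YABBY transcription factor (449 ± 47.4 against 39.7 ± 16.0), AT4G14130, a xyloglucan endotransglucosylase that loosens walls (2399 ± 285 against 361 ± 122), and AT3G28390, an ABC transporter (4299 ± 348 against 667 ± 417). In all, limma called 1516 genes, 1022 higher and 494 lower. The 67.4% that were higher became 33.1% under median-of-ratios scaling, which moved the median change of all genes from 0.21 to 0.01, and 52.2% under quantile normalisation. As lists, photosynthesis (adjusted p = 3.43e-13, and adjusted p = 0.452 with an estimated correlation) and heat shock (adjusted p = 1.0e-08, and adjusted p = 0.466 with an estimated correlation) were lower than other genes. The starch synthesis, jasmonate, morning clock and endoplasmic reticulum folding lists were lower too, and lost their calls at adjusted p = 0.534, 0.534, 0.452 and 0.576 with an estimated correlation. For the sucrose and evening clock lists median and mean were above 0 while the test pointed down (adjusted p = 0.697 and 0.708). In 39.1% of genes the groups did not overlap, where chance gives 10% if all libraries are independent. Noon samples 1 and 3 may not be, and for 2 libraries against 3 chance gives 20%. Likeness among the noon libraries would raise it further.

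These noon calls depend on single libraries. With both near-identical pairs, at noon and without ants, taken as 1 library each, limma called 95 genes, 11 higher and 84 lower. Of the list members above 3 passed, all photosynthesis genes. The pair without ants enters this count only through the shared spread. The count was 2595 without 9 am sample 1, 140 without 9 am sample 3, and 219, 220 and 188 without noon samples 1, 2 and 3. It was 626 in a fit of these groups alone, 390 with the sample number as a replicate block in that fit and 802 at a change of at least 2-fold.

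Nectaries at 3 pm and at 3 am were each set against 9 am, and in neither comparison did a gene pass. At 3 pm SWEET9 averaged 9709 ± 9372 (adjusted p = 0.166), CWINV4 8023 ± 4550 (adjusted p = 0.218), SPS1F 7881 ± 1793 (adjusted p = 0.345), LHY 5577 ± 6099 (adjusted p = 0.208), TOC1 4558 ± 1077 (adjusted p = 0.142) and GI 19916 ± 19298 (adjusted p = 0.707). At 3 am SWEET9 averaged 84472 ± 64261 (adjusted p = 0.550), CWINV4 44794 ± 6575 (adjusted p = 0.184), SPS1F 7737 ± 776 (adjusted p = 0.523), LHY 67854 ± 21459 (adjusted p = 0.374), TOC1 748 ± 115 (adjusted p = 0.307) and GI 7736 ± 1050 (adjusted p = 0.914). For 3 pm limma called 0 genes, with 2255 at an unadjusted p under 0.05 and a smallest adjusted p of 0.133, and the groups did not overlap in 9.15% of genes, where chance gives 10%. For 3 am it called 0, with 1610 at an unadjusted p under 0.05 and a smallest adjusted p of 0.132, and the groups did not overlap in 19.7%, where chance gives 20%. Adjusted over the list alone, 5 of 9 evening clock and 2 of 4 nectary development genes were higher at 3 pm, and of the jasmonate genes 1 was higher and 1 lower. At 3 am 12 of 21 phenylpropanoid genes, 3 heat shock genes, 2 each of starch synthesis, sucrose and drought, and 1 each of jasmonate, salicylate and cuticle were higher, adjusted over the list alone. As lists, photosynthesis (adjusted p = 8.69e-11, and adjusted p = 0.452 with an estimated correlation), heat shock (adjusted p = 2.75e-06, and adjusted p = 0.534 with an estimated correlation) and xylem (adjusted p = 0.000710, and adjusted p = 0.576 with an estimated correlation) were lower at 3 pm than at 9 am, as were the morning clock, starch synthesis, salicylate, endoplasmic reticulum, phenylpropanoid and cell cycle lists, at adjusted p from 0.452 to 0.674 with an estimated correlation. At 3 am phenylpropanoid genes were higher (adjusted p = 4.46e-08, and adjusted p = 0.466 with an estimated correlation), as were photosynthesis, heat shock, cell cycle, xylem and drought genes, at adjusted p from 0.452 to 0.611 with an estimated correlation, and starch breakdown was lower (adjusted p = 0.0448, and adjusted p = 0.611 with an estimated correlation). The guard cell and cuticle lists at 3 pm, and the jasmonate list at 3 am, had a median above 0 while the test pointed down.

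Single libraries decide these counts of 0. For 3 pm the count was 802 without 9 am sample 1, 113 without 9 am sample 2, 426 without 3 pm sample 1 and 367 without 3 pm sample 3, and 1 with the sample number as a replicate block. For 3 am it was 869 without 9 am sample 3, 1 without 3 am sample 1 and 86 with that block in these groups alone.

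Night was compared with afternoon directly, 3 am against 3 pm. At night 17 of 33 photosynthesis, 14 of 21 phenylpropanoid, 9 of 12 xylem and 10 of 14 heat shock genes rose, and 3 of 19 sucrose genes. CWINV4, an invertase that splits sucrose in the wall of nectary cells, rose to 44794 ± 6575 from 8023 ± 4550 (log2 fold change 2.61 ± 0.45, adjusted p = 0.00271), and CWINV2 to 7562 ± 1044 from 1295 ± 878. SWEET9 rose to 84472 ± 64261 from 9709 ± 9372 (adjusted p = 0.0111), while the hexose transporter STP1 fell, so that 3 of 19 sucrose genes rose and 1 fell (3 and 1 adjusted over the list alone). APS1, APL1 and APL3, subunits of the enzyme that commits glucose to starch, rose as 3 of 16 starch synthesis genes (4 adjusted over the list alone), whereas 6 of 19 starch breakdown genes fell, among them GWD1 and SEX4 (8 down and 1 up adjusted over the list alone). LHY rose to 67854 ± 21459 from 5577 ± 6099 and TOC1 fell to 748 ± 115 from 4558 ± 1077. With LHY rose LNK1 and LNK2, 3 of 7 morning clock genes, and with TOC1 fell ELF3, ELF4 and FKF1, 4 of 9 evening clock genes (3 up and 1 down, and 1 up and 4 down, adjusted over the list alone).

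Of the 14 heat shock genes 10 rose (11 adjusted over the list alone), with HSP101, a chaperone that dissolves protein aggregates, at 29762 ± 14207 against 1061 ± 479. Photosynthesis genes rose in 17 of 33 (20 adjusted over the list alone), with LHCB5 at 18770 ± 5026 against 2267 ± 2512. Phenylpropanoid genes rose in 14 of 21 (16 adjusted over the list alone), with the flavonoid enzyme F3H at 9542 ± 47.4 against 2692 ± 218. Beside them xylem genes rose in 9 of 12 (9 adjusted over the list alone), with MYB46, a switch for secondary walls, at 146 ± 42.4 against 16.0 ± 9.64, and cell cycle genes in 9 of 18 (11 adjusted over the list alone), with the replication helicase subunit MCM5 at 300 ± 107 against 60 ± 38.9. Of 23 salicylate and pathogen genes 3 rose and 3 fell (3 and 3 adjusted over the list alone). PR1, a salicylate-induced defence protein, rose to 6590 ± 1720 from 507 ± 30.1, and FMO1, an enzyme of systemic resistance, fell to 333 ± 2.83 from 2096 ± 1078. Of 16 jasmonate genes 4 rose, among them OPR3 and JAZ1, and 2 fell (6 and 3 adjusted over the list alone), among them COI1, the jasmonate receptor, at 4842 ± 453 against 12729 ± 1718. The lipid transfer protein LTP1 rose to 31570 ± 6558 from 6273 ± 4607, among 2 of 8 cuticle and epidermis genes that rose (2 adjusted over the list alone). Of the remaining lists 1 of 5 guard cell genes (1 adjusted over the list alone), 2 of 9 endoplasmic reticulum genes (5 adjusted over the list alone) and 3 of 7 drought genes (3 adjusted over the list alone) rose. No nectary development or phloem gene passed. SPS1F (adjusted p = 0.994) averaged 7737 ± 776 against 7881 ± 1793, and GI (adjusted p = 0.485) 7736 ± 1050 against 19916 ± 19298.

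In all, limma called 2400 genes between 3 am and 3 pm, 1264 higher and 1136 lower. The 52.7% that were higher became 40.3% under quantile normalisation. As lists, photosynthesis (adjusted p = 1.0e-08, and adjusted p = 0.452 with an estimated correlation), phenylpropanoids (adjusted p = 1.4e-06, and adjusted p = 0.534 with an estimated correlation), heat shock (adjusted p = 4.71e-06, and adjusted p = 0.534 with an estimated correlation) and xylem (adjusted p = 0.000443, and adjusted p = 0.576 with an estimated correlation) were higher at 3 am, and so were the cell cycle, endoplasmic reticulum and drought lists, at adjusted p = 0.534, 0.662 and 0.452 with an estimated correlation. The groups did not overlap in 41.1% of genes, where chance gives 20%. The count was 574 without 3 am sample 1, and 585 without 3 am sample 2. It was 3 in a fit of these groups alone, 445 with the sample number as a replicate block in that fit, and 1387 at a change of at least 2-fold.

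The 8 am controls were set against 9 am to show how far morning samplings differ. Of 19 sucrose genes 7 rose and none fell (8 adjusted over the list alone). CWINV4 rose to 85673 ± 15035 from 15603 ± 7961 (log2 fold change 2.56 ± 0.41, adjusted p = 0.000829), CWINV2 to 13989 ± 2887 from 2149 ± 674, and SUS1, a sucrose synthase, to 38847 ± 4385 from 13077 ± 3710. SWEET9 rose to 174589 ± 43459 from 55009 ± 69275 (adjusted p = 0.0300), though the libraries overlapped. Of 16 starch synthesis genes APS1, APL1 and APL3 rose (3 up and 1 down adjusted over the list alone). Of 19 starch breakdown genes AMY2, GWD1 and PWD fell and AMY1 rose (5 down and 1 up adjusted over the list alone). Of 21 phenylpropanoid genes 9 rose (12 adjusted over the list alone), with HCT at 6943 ± 1196 against 2108 ± 267. Of 18 cell cycle genes 5 rose (8 up and 1 down adjusted over the list alone), and 4 of 33 photosynthesis genes rose (4 adjusted over the list alone), which became 0 under quantile normalisation. Among markers of other cell types the xylem list had a median log2 change of 1.33 with no member past the threshold, as the phloem list did at 0.16. The cuticle genes LACS2 and CER6, 2 of 8, and the guard cell gene KAT1, 1 of 5, rose (2 and 2 adjusted over the list alone). LHY, the 1 of 7 morning clock genes that rose (1 adjusted over the list alone), stood at 118171 ± 19186 against 35452 ± 42257, a call that both other scalings ended. Of 9 evening clock genes 2 rose (2 adjusted over the list alone). EP3, a chitinase, rose to 5142 ± 2905 from 323 ± 277, and FMO1 fell to 243 ± 15.5 from 1354 ± 995, so that 2 of 23 salicylate and pathogen genes rose and 1 fell (2 and 1 adjusted over the list alone). Of the remaining lists 1 of 16 jasmonate and 1 of 14 heat shock genes rose and 1 of 4 nectary development genes fell (the same counts adjusted over the list alone). No endoplasmic reticulum or drought gene passed. SPS1F averaged 6102 ± 389 against 6102 ± 1475 (adjusted p = 0.951), TOC1 942 ± 41.4 against 2182 ± 1602 (adjusted p = 0.196) and GI 3926 ± 743 against 11433 ± 9663 (adjusted p = 0.209).

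Against 9 am limma called 1743 genes in the 8 am controls, 1337 higher and 406 lower. The 76.7% that were higher became 50.1% under median-of-ratios scaling, which moved the median change of all genes from 0.14 to 0.00, and 44.8% under quantile normalisation. As lists, phenylpropanoids (adjusted p = 0.000494, and adjusted p = 0.576 with an estimated correlation) and sucrose genes (adjusted p = 0.00742, and adjusted p = 0.534 with an estimated correlation) were higher and starch breakdown lower (adjusted p = 0.0107, and adjusted p = 0.534 with an estimated correlation). The photosynthesis and cell cycle lists were higher too, both at adjusted p = 0.662 with an estimated correlation. Median, mean and test differed in sign for the starch synthesis, jasmonate, salicylate, endoplasmic reticulum, phloem and guard cell lists, none of which passed as a list. The groups did not overlap in 27.2% of genes, where chance gives 10%. The count was 863 without 9 am sample 1, 2934 without 9 am sample 3, and 885, 1103 and 970 without 8 am samples 1, 2 and 3. It was 1761 with the sample number as a replicate block, 474 with that block in these groups alone, 14 in these groups alone without the block, 947 with array quality weights and 839 at a change of at least 2-fold.

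Nectaries after 2 days without the resident ants were compared with the 8 am controls. Of 21 phenylpropanoid genes 15 fell and none rose (18 fell adjusted over the list alone). PAL1, PAL2 and PAL4, which open the pathway, fell, PAL4 to 1148 ± 71.8 from 12642 ± 3691 (log2 fold change -3.42 ± 0.41, adjusted p = 4.95e-05). The secondary-wall cellulose synthase CESA4 fell to 96.0 ± 7.94 from 2429 ± 1203 and the wall protein FLA11 to 45.7 ± 11.6 from 1976 ± 1268, among 9 of 12 xylem genes that fell and 1 that rose (10 and 1 adjusted over the list alone). The phloem genes SUC2 and SEOR1, 2 of 5, fell with them (6638 ± 863 against 14518 ± 1566 and 4919 ± 874 against 16388 ± 4688; 2 adjusted over the list alone). LTP1, the 1 of 8 cuticle and epidermis genes that fell (1 adjusted over the list alone), stood at 730 ± 296 against 19049 ± 7622. Guard cell genes had a median log2 change of -0.51 over 5 members, and no member passed. Cell cycle genes fell in 9 of 18 cases and rose in 1 (11 and 1 adjusted over the list alone), with the helicase subunit MCM6 at 70.0 ± 18.3 against 412 ± 199.

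CWINV4 fell to 11309 ± 2365 from 85673 ± 15035 (log2 fold change -2.93 ± 0.41, adjusted p = 0.000124) and CWINV2 to 1612 ± 407 from 13989 ± 2887, while SWEET9 averaged 242141 ± 80845 against 174589 ± 43459 (adjusted p = 0.685). Of 19 sucrose genes 6 fell and 2 rose (8 and 2 adjusted over the list alone). APL1, APS1, APL3 and PGM1 were the 4 of 16 starch synthesis genes that fell, with 1 that rose (4 and 1 adjusted over the list alone). AMY1, AMY3, BAM9 and PWD of the starch breakdown list rose as 4 of 19 (1 adjusted over the list alone). Of 33 photosynthesis genes 17 fell and 1 rose (22 and 1 adjusted over the list alone), with LHCB4.1 at 2044 ± 216 against 9446 ± 3367. Of 14 heat shock genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with HSP101 at 1013 ± 91.8 against 13773 ± 9318. The nectary development genes BOP1 and PIN6, 2 of 4, fell (2 adjusted over the list alone). Of 7 drought genes 2 fell (2 adjusted over the list alone), and no endoplasmic reticulum gene passed.

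PR4 rose to 8443 ± 807 from 2137 ± 480 and the glucanase BGL2 to 1617 ± 520 from 437 ± 97.7 (adjusted p = 0.0220), while the chitinase EP3 fell to 126 ± 58.5 from 5142 ± 2905, so that 3 of 23 salicylate and pathogen genes rose and 2 fell (3 and 2 adjusted over the list alone). JAR1, which makes the active jasmonate conjugate, rose to 23536 ± 606 from 5620 ± 1203 (adjusted p = 1.86e-05), MYC2, the main jasmonate transcription factor, rose to 30453 ± 2517 from 15686 ± 2885, and the biosynthesis genes OPR3 and LOX3 fell. Of 16 jasmonate genes 3 rose and 2 fell (4 and 2 adjusted over the list alone). PR1 averaged 3165 ± 2192 against 3565 ± 1787 (adjusted p = 0.683) and LOX2 15671 ± 1706 against 19293 ± 448 (adjusted p = 0.449). In the clock lists RVE8 rose to 703 ± 378 from 141 ± 18.3, GI fell to 773 ± 358 from 3926 ± 743 and ELF3 rose, and the other clock genes measured did not pass (1 up in the morning list, 1 up and 1 down in the evening list, also adjusted over the list alone). The largest changes included MLP-like protein AT1G24020 (61.0 ± 20.3 against 13664 ± 7530) and the trehalose-phosphate synthase AT1G70290, which rose to 818 ± 80.4 from 40.7 ± 3.79.

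In all, limma called 3368 genes after removal of the ants, 1421 higher and 1947 lower. The 42.2% that were higher became 56.4% under quantile normalisation. As lists, phenylpropanoids (adjusted p = 1.45e-08, and adjusted p = 0.452 with an estimated correlation), xylem (adjusted p = 1.3e-05, and adjusted p = 0.534 with an estimated correlation), photosynthesis (adjusted p = 0.000227, and adjusted p = 0.576 with an estimated correlation) and cell cycle genes (adjusted p = 0.00311, and adjusted p = 0.576 with an estimated correlation) were lower. So were the starch synthesis and heat shock lists, at adjusted p = 0.611 and 0.725 with an estimated correlation. Median and mean differed in sign for the sucrose list (0.06 and -0.77) and for the morning clock, jasmonate, salicylate and drought lists, none of which passed, and for the evening clock list both were below 0 while the test pointed up. The groups did not overlap in 53.2% of genes, where chance gives 10% if all libraries are independent. Samples 2 and 3 without ants may not be, and for 2 libraries against 3 chance gives 20%. With both near-identical pairs, at noon and without ants, taken as 1 library each, limma called 1816 genes, 655 higher and 1161 lower. Among them 13 phenylpropanoid and 8 xylem genes fell. The count was 1955 without 8 am sample 2, and 2148 and 2128 without samples 2 and 3 of the group without ants. It was 1901 at a change of at least 2-fold, 6963 with array quality weights and 5625 in a fit without the 9 am and 3 pm groups.

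**Figure D3:**
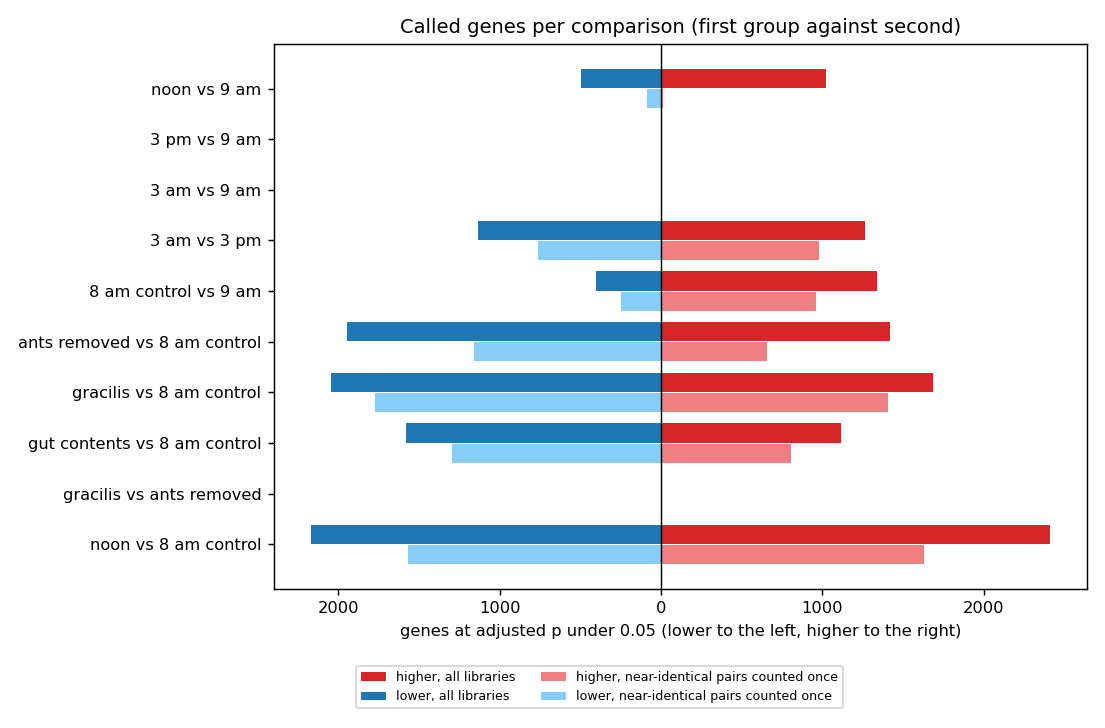
Genes at an adjusted p under 0.05 (limma) in each comparison, higher to the right and lower to the left of 0, with all libraries (dark bars) and with each near-identical pair counted as 1 library (light bars). For noon against 9 am the count goes from 1516 to 95 and for removal of the ants from 3368 to 1816; noon against 8 am was added after the data were seen.

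The Gracilis treatment was compared with the same controls. The phenylpropanoid genes PAL1, PAL2, PAL4 and F3H fell, F3H to 941 ± 347 from 6567 ± 2656 (log2 fold change -2.80 ± 0.35, adjusted p = 7.1e-05), among 15 of 21 that fell (17 adjusted over the list alone). COBL4, a protein of secondary walls, fell to 77.0 ± 54.8 from 2352 ± 1038 among 8 of 12 xylem genes that fell and 1 that rose (9 and 1 adjusted over the list alone). SUC2 and SEOR1, 2 of 5 phloem genes, and LTP1, 1 of 8 cuticle and epidermis genes, fell too (2 and 1 adjusted over the list alone). The guard cell list had a median of -0.36, which became 0.37 under quantile normalisation. CWINV4 fell to 8735 ± 2476 from 85673 ± 15035 (log2 fold change -3.32 ± 0.41, adjusted p = 5.67e-05), among 8 of 19 sucrose genes that fell and 2 that rose (8 and 3 adjusted over the list alone). SWEET9 averaged 180047 ± 19956 against 174589 ± 43459 (adjusted p = 0.949). Cell cycle genes fell in 12 of 18 cases (14 adjusted over the list alone), with PCNA1, the replication clamp, at 259 ± 20.6 against 1091 ± 514. Photosynthesis genes fell in 14 of 33 (20 down and 2 up adjusted over the list alone), with 1 that rose, heat shock genes in 6 of 14 (6 adjusted over the list alone) and starch synthesis genes in 6 of 16, with 1 that rose (7 and 1 adjusted over the list alone). PR4 rose to 8114 ± 1300 and BGL2 to 2210 ± 1269 from 437 ± 97.7 (adjusted p = 0.00915), while EP3 fell to 178 ± 108, so that 5 of 23 salicylate and pathogen genes rose and 3 fell (6 and 3 adjusted over the list alone). JAR1 rose to 25152 ± 2626 and MYC2 to 29630 ± 4980 (adjusted p = 0.0298), while LOX3 fell, so that 4 of 16 jasmonate genes rose and 1 fell (4 and 1 adjusted over the list alone). PR1 averaged 1647 ± 809 (adjusted p = 0.280) and LOX2 16600 ± 738 (adjusted p = 0.592). In the clock lists RVE8, 1 of 7 morning genes, rose to 768 ± 384 and GI fell to 712 ± 71.0, while 1 other of the 9 evening genes rose (the same counts adjusted over the list alone). Of the remaining lists 4 of 19 starch breakdown genes rose (4 adjusted over the list alone). Of 4 nectary development genes 2 fell and 1 rose (2 and 1 adjusted over the list alone), and 2 of 9 endoplasmic reticulum genes (1 adjusted over the list alone) and 2 of 7 drought genes (2 adjusted over the list alone) fell.

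For Gracilis limma called 3729 genes, 1684 higher and 2045 lower. The 45.2% that were higher became 56.8% under quantile normalisation. As lists, phenylpropanoids (adjusted p = 6.52e-08, and adjusted p = 0.466 with an estimated correlation), cell cycle (adjusted p = 5.3e-05, and adjusted p = 0.534 with an estimated correlation), xylem (adjusted p = 9.23e-05, and adjusted p = 0.534 with an estimated correlation) and photosynthesis (adjusted p = 0.000701, and adjusted p = 0.589 with an estimated correlation) were lower. So were the heat shock and starch synthesis lists, at adjusted p = 0.662 and 0.611 with an estimated correlation. Median and mean differed in sign for the sucrose (0.05 and -0.84), clock, salicylate and drought lists, none of which passed. The groups did not overlap in 54.3% of genes, where chance gives 10%. The count was 2326 without 8 am sample 2 and 2422 without Gracilis sample 2. It was 2039 at a change of at least 2-fold, 6489 with array quality weights and 5921 in a fit without the 9 am and 3 pm groups.

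The gut contents treatment, with 2 libraries, was set against the same controls. PAL1, PAL2, PAL4 and the anthocyanidin enzyme LDOX fell, PAL1 to 85.5 ± 17.7 from 1704 ± 454 (log2 fold change -4.28 ± 0.53, adjusted p = 0.000133), among 13 of 21 phenylpropanoid genes that fell (15 adjusted over the list alone). CESA4 fell to 106 ± 41.0 from 2429 ± 1203 among 9 of 12 xylem genes that fell and 1 that rose (10 and 1 adjusted over the list alone). LTP1, 1 of 8 cuticle and epidermis genes, fell to 778 ± 70.0 (1 adjusted over the list alone). The guard cell list had a median of -0.36, which became 0.41 under quantile normalisation, and the phloem list had a median of -1.07, with no member past the threshold in either. Cell cycle genes fell in 13 of 18 cases (16 adjusted over the list alone), with MCM4 at 40.5 ± 9.19 against 462 ± 276. CWINV4 fell to 13352 ± 9021 (log2 fold change -2.85 ± 0.45, adjusted p = 0.000526) and CWINV2 to 1948 ± 1272, among 5 of 19 sucrose genes that fell and 2 that rose (5 and 2 adjusted over the list alone). SWEET9 averaged 232610 ± 76360 (adjusted p = 0.756). Photosynthesis genes fell in 10 of 33 (19 down and 1 up adjusted over the list alone), heat shock genes in 5 of 14 (5 adjusted over the list alone) and starch synthesis genes in 4 of 16, with 1 that rose (4 and 1 adjusted over the list alone). PR4 rose to 9810 ± 1516 and BGL2 to 1874 ± 772 (adjusted p = 0.0272), and EP3 fell to 100 ± 14.1, so that 3 of 23 salicylate and pathogen genes rose and 1 fell (3 and 1 adjusted over the list alone). Of 16 jasmonate genes 1 rose, JAR1 to 25232 ± 4189, and 2 fell, OPR3 to 853 ± 255 from 1774 ± 707 and LOX3 (2 and 2 adjusted over the list alone). PR1 averaged 3684 ± 3483 (adjusted p = 0.870), MYC2 30680 ± 8888 (adjusted p = 0.0535) and LOX2 17828 ± 3112 (adjusted p = 0.811). Of the remaining lists 1 of 19 starch breakdown genes rose and 2 of 4 nectary development and 2 of 7 drought genes fell (the same counts adjusted over the list alone). No clock or endoplasmic reticulum gene passed. GI averaged 991 ± 48.1 against 3926 ± 743 in the controls, near its 712 ± 71.0 for Gracilis, where it passed. Its SD was 9663 at 9 am and 19298 at 3 pm, and this spread enters the test. With 2 libraries here, a missed call does not show that clock genes were unchanged.

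With gut contents limma called 2702 genes, 1118 higher and 1584 lower. The 41.4% that were higher became 55.5% under quantile normalisation. As lists, phenylpropanoids (adjusted p = 1.0e-08, and adjusted p = 0.452 with an estimated correlation), cell cycle (adjusted p = 6.02e-07, and adjusted p = 0.452 with an estimated correlation), xylem (adjusted p = 9.96e-06, and adjusted p = 0.534 with an estimated correlation) and photosynthesis (adjusted p = 6.88e-05, and adjusted p = 0.534 with an estimated correlation) were lower. So were the heat shock and starch synthesis lists, at adjusted p = 0.683 and 0.611 with an estimated correlation. Median and mean differed in sign for the sucrose (0.02 and -0.75), salicylate and drought lists, and for the evening clock and jasmonate lists both were below 0 while the test pointed up; none of these passed. The groups did not overlap in 57.3% of genes, where chance gives 20%. The count was 920 without gut contents sample 1, 1630 without sample 2, and 1515 without 8 am sample 2. It was 971 without sample 1 of each ant treatment, 1725 at a change of at least 2-fold and 5161 in a fit without the 9 am and 3 pm groups.

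A direct test of Gracilis against removal of the ants, which uses no control library, asked whether these treatments differ. CWINV4 averaged 8735 ± 2476 for Gracilis and 11309 ± 2365 without ants, SWEET9 180047 ± 19956 and 242141 ± 80845, PR1 1647 ± 809 and 3165 ± 2192, BGL2 2210 ± 1269 and 1617 ± 520, MYC2 29630 ± 4980 and 30453 ± 2517, and LOX2 16600 ± 738 and 15671 ± 1706. None of these 6 genes passed (limma, adjusted p = 1 for each). Of 12264 genes limma called 0, with 76 at an unadjusted p under 0.05 where chance alone gives 613.2, and the groups did not overlap in 5.85% of genes, where chance gives 10%. So few small p-values point to a conservative test. The scattered time-course groups are not compared here but widen the shared error, so the count of 0 is weak evidence of no difference. In a fit without those groups it stayed 0, with 260 at an unadjusted p under 0.05, still fewer than chance gives. By a normal approximation, the 95% interval of a gene's change reached a median 0.51 to either side on the log2 scale. At the widest decile it reached 1.21, so smaller differences are not excluded. The degrees of freedom of the fit would widen these intervals slightly. The shared error, likely too large here, acts the other way. The count stayed 0 with the sample number as a replicate block (92 at an unadjusted p under 0.05) and was 343 with array quality weights. As lists, cell cycle (adjusted p = 2.27e-05, and adjusted p = 0.534 with an estimated correlation) and heat shock genes (adjusted p = 0.0480, and adjusted p = 0.725 with an estimated correlation) were lower and xylem genes higher (adjusted p = 0.0406, and adjusted p = 0.682 with an estimated correlation) for Gracilis. The phloem list had a median above 0 and a mean below 0.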

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

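The tests of explanations below, the test of gut contents against removal of the ants, the rescaled counts of single libraries and the splits for noon against 8 am were chosen after the values had been seen; the other counts over splits of the libraries were planned.

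The gut contents treatment was tested directly against removal of the ants, because both were set against the same controls. Of 12264 genes limma called 8, all lower with gut contents. An unadjusted p under 0.05 was found for 111, where chance alone gives 613.2. The shared error is likely too large here, because the scattered time-course groups widen it. In a fit without those groups limma called 6, with 245 at an unadjusted p under 0.05. The 8 genes were chosen after their values were seen. With gut contents AT5G47635, AT2G21100, AT5G09520, AT5G13580 and AT1G74460 averaged 3.0, 6.0, 5.5, 6.0 and 1.5, at the floor of the values. The proline-rich wall protein AT5G09530 averaged 37.5 ± 16.3 with gut contents and 1841 ± 971 without ants, against 85.3 ± 43.8 in the controls (adjusted p = 0.0164), and the acyltransferase AT5G41040 averaged 53.5 ± 4.95 and 480 ± 242, against 356 ± 127. With both near-identical pairs, at noon and without ants, taken as 1 library each, limma called 0 genes, with 62 at an unadjusted p under 0.05. The log2 change of AT5G09530 went from -5.45 ± 0.76 SE to -5.17 ± 0.86 and that of AT5G41040 from -2.97 ± 0.45 to -2.70 ± 0.50. Over the 8 genes the change was a median 0.95 times and its error 1.15 times that of the main fit. This fit has 1 library fewer in the group without ants and 1 fewer at noon. These values therefore do not show that the loss comes from the pair without ants. The count was also 0 without sample 2 or without sample 3 of that group (80 and 70 at an unadjusted p under 0.05), in a fit of these groups alone (165), under quantile normalisation (98) and without sample 1 of each ant treatment (253), and 1 without gut contents sample 1 and 4 without sample 2. Gut contents against Gracilis gave 0 calls in limma, with 72 genes at an unadjusted p under 0.05, where chance alone gives 613.2. This test has the same shared error, so its count of 0 is weak evidence of no difference.

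The 2 pm library and the library with returned ants enter no comparison. In the 2 pm library 1954 genes lay over 2-fold above all 3 of the 8 am controls and 344 over 2-fold below. The library as a whole lay higher, with a median value of 930 against 651 to 669.5 in the controls. After median-of-ratios rescaling the counts were 800 above and 751 below. In the library with returned ants 342 lay above and 1069 below (337 and 1083 rescaled). Each control set in the same way against the other 2 gave 109, 275 and 163 genes above and 213, 58 and 209 below (111, 306 and 153 above and 219, 54 and 227 below rescaled).

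The libraries labelled 9 am and 3 pm lay nearest to libraries of other groups, as did 6 of the 16 other libraries with replicates. Of the 9 am and 3 pm libraries 6 stayed nearest to another group by rank correlation. Rescaling changed 0 nearest libraries by the correlation of log2 values. A scaling factor per library cannot change rank correlations, so the rank test could not have come out otherwise. By that arithmetic such a factor cannot produce a pattern in ranks, whatever the values, so the rank test adds no evidence on scaling. Scaling that differs between genes was not tested. In 6 of the 9 am and 3 pm libraries the 16 clock genes also lay closer to the library nearest on all other genes than to any of their own group. A wrong time label would give this, and in 4 of the 6 others the clock genes did so too. Plants of different light history or clock phase, pooled under a right label, would give the same, and plant-to-plant differences were not tested. The labels hold nothing that settles which applies, and no library was moved to another group.

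The ant treatments and the library with returned ants lay apart from the 8 am controls. The clock genes had a median absolute log2 change of 0.88, at percentile 99.62 of 10000 random lists of similar mean value, so another clock time than the controls may contribute; clock genes also vary widely between libraries, which makes this a weak test. Less vascular tissue would lower phloem and xylem alike, and their medians were -1.11 and -3.99, a difference of 2.88 with an exact permutation p of 0.160 over 6188 regroupings, which decides nothing. If absence of the resident ants were the cause, their return could bring values back, but the library with returned ants lay at 0.830 on a scale from the controls (0) to the libraries without ants (1), which themselves lay at 0.772, 1.005 and 0.998, and the time since the return is not given in the sources used here. The labels give no sampling day or batch for the ant treatments. Either could go with the treatments and neither was tested, so the effect of the ants cannot be told apart from them.

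With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For noon against 9 am the real split called 1516 genes and the highest other 0, so 1 of the 10 splits gave as many. For 8 am against 9 am these counts were 1743 and 101 (1 split), for removal of the ants 3368 and 1 (1 split), for Gracilis against the controls 3729 and 0 (1 split) and for noon against 8 am 4585 and 0 (1 split). For Gracilis against removal of the ants limma called 0 in the real split, with 76 genes at an unadjusted p under 0.05, and 0 in the others. For 3 pm against 9 am limma called 0 in the real split, with 2255 at an unadjusted p under 0.05. A count of 0 is matched by any split, so for these 2 comparisons the tally of 10 splits was fixed beforehand and says nothing. Of the 9 other splits for 3 pm against 9 am, 1 gave 2861 genes (3 pm sample 1 with 9 am samples 2 and 3) and 1 gave 2415 (3 pm samples 1 and 2 with 9 am sample 2), while the rest gave 0 to 43 (median of the 9 others 1); these 2 counts point to a structure among the 6 libraries other than their labels.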

How the results depend on the processing

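Chosen after the data were seen were the near-identical pairs as 1 library, the fits without 9 am and 3 pm, the alternatives without sample 1 of each ant treatment, the replicate block in the compared groups alone, the rescaled counts of single libraries, and all alternatives for noon against 8 am and for gut contents against removal of the ants. The count-based test was not run, because the values are not raw counts. Pseudocounts of 0.1 and 10, both filters and both scalings left the total of called genes in the F test and in each comparison of 2 groups within 1.5 times its main value, except for gut contents against removal of the ants. The split by direction moved further under the scalings. At noon against 9 am 1022 higher genes became 345 (median-of-ratios) and 494 lower genes 784 (quantile). At 8 am against 9 am 1337 higher genes became 833 and 764 and 406 lower genes 830 and 942 (median-of-ratios and quantile), and at 3 am against 3 pm 1136 lower genes became 1927 (quantile). Unless stated, the cause of a change was not tested.

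With each near-identical pair as 1 library the F test called 3200 genes, noon against 9 am 95 and removal of the ants 1816; fewer libraries enter these tests. Other counts were 1747 for 3 am against 3 pm, 1211 for 8 am against 9 am, 3183 for Gracilis, 2105 for gut contents and 3198 for noon against 8 am.

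In a fit of only the groups compared, which leaves fewer libraries for the spread, the counts were 2985 for the F test, 626 for noon against 9 am, 3 for 3 am against 3 pm, 14 for 8 am against 9 am and 6994 for noon against 8 am. Array quality weights gave 7315 for the F test, 947 for 8 am against 9 am, 6963 for removal of the ants, 6489 for Gracilis, 343 for Gracilis against removal of the ants, where the report has 0 (limma, 76 at an unadjusted p under 0.05), and 7466 for noon against 8 am. A change of at least 2-fold, a stricter demand by construction, left 3167 genes in the F test, 802 at noon against 9 am, 1387 at 3 am against 3 pm, 839 at 8 am against 9 am, 1901 for removal of the ants, 2039 for Gracilis, 1725 for gut contents and 2436 for noon against 8 am. Without the 8 am group the F test called 2678. Without the scattered 9 am and 3 pm groups in the spread, the counts were 5625 for removal of the ants, 5921 for Gracilis and 5161 for gut contents. In that fit limma called 0 for Gracilis against removal of the ants, with 260 at an unadjusted p under 0.05. Without sample 1 of each ant treatment gut contents gave 971.

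With the sample number as a replicate block 3 pm against 9 am gave 1 gene. With that block in the compared groups alone the counts were 390 for noon against 9 am, 86 for 3 am against 9 am, 445 for 3 am against 3 pm and 474 for 8 am against 9 am. For noon against 9 am the paired libraries correlated at -0.15 to -0.02, so the numbers do not pair them.

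Leaving out 1 library at a time, which at 3 am or with gut contents leaves a lone library assumed to vary like the other groups, gave 3677 to 5456 genes in the F test, 140 to 2595 for noon against 9 am, 0 to 802 for 3 pm against 9 am, 0 to 869 for 3 am against 9 am, 574 to 2850 for 3 am against 3 pm and 863 to 2934 for 8 am against 9 am. It gave 1955 to 2997 for removal of the ants, 2326 to 3212 for Gracilis, 920 to 2331 for gut contents, 0 in every case for Gracilis against removal of the ants and 3400 to 3826 for noon against 8 am. The extremes come without 9 am sample 1 (2595, 802 and 863), 9 am sample 3 (140, 869 and 2934), 3 am sample 1 (574), 8 am sample 2 (1955 and 2326) and gut contents sample 1 (920). List calls ranged from 46 to 62 of 162, against 55 in the report, and were 0 with an estimated correlation.

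Gut contents against removal of the ants, with 8 genes, gave 4 with a pseudocount of 10, 5 with the higher filter, 19 with array quality weights, 3 with the replicate block in these groups alone and 0 to 9 without single libraries. In limma it gave 0 under quantile normalisation (98 at an unadjusted p under 0.05) and in a fit of these groups alone (165). With both near-identical pairs taken as 1 library each it also gave 0 (62 at an unadjusted p under 0.05).

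Among named genes, 1432 results kept direction and side of the threshold for removal of the ants, 109 lost the call, 1 gained it and 3 changed sign; for noon against 9 am these counts were 759, 330, 2 and 2, and for 8 am against 9 am 780, 250, 1 and 5. The genes that changed sign were not called in the report either. SPS1F at 3 am against 3 pm went to 0.046 under median-of-ratios scaling, 0.077 with weights, 0.023 with the replicate block, 0.13 with the block in these groups alone and -0.20 to 0.13 without single libraries. At 8 am against 9 am SPS1F went to -0.11 and -0.23 under median-of-ratios and quantile scaling and to -0.11 to 0.21 without single libraries. PR1 after removal of the ants went to 0.32 with weights, 0.45 without sample 1 and -0.97 to 0.45 without single libraries, and with gut contents to 0.075 with the mean of 8 and 9 am as control, 0.93 without sample 1 and -1.40 to 0.93 without single libraries. LOX2 with gut contents went to 0.054 without sample 1, and to -0.30 to 0.054 without single libraries. Gracilis against removal of the ants gave LOX2 -0.026 with weights and, without single libraries, LOX2 -0.0058 to 0.14, BGL2 -0.12 to 0.90 and MYC2 -0.14 to 0.097. Without single libraries, GI ranged from -0.26 to 0.86 and CWINV4 from -0.071 to 0.63 at noon against 9 am. GI ranged from -0.34 to 1.46 at 3 pm against 9 am, from -0.71 to 0.41 at 3 am against 9 am and from -1.70 to 0.098 at 3 am against 3 pm, and SWEET9 for Gracilis from -0.15 to 0.21.

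Scaling moved the median change of all genes from 0.14 to -0.01 for 3 pm and from 0.13 to 0.02 for 3 am against 9 am (median-of-ratios), and under quantile normalisation from -0.05 to 0.09 for removal of the ants, -0.03 to 0.09 for Gracilis and -0.01 to 0.11 for gut contents. List medians changed sign under at least 1 scaling for cuticle at 3 pm, jasmonate at 3 am, starch synthesis, salicylate, endoplasmic reticulum folding and phloem at 8 am against 9 am, evening clock after removal of the ants, guard cells for Gracilis, evening clock, drought and guard cells for gut contents, and sucrose for Gracilis against removal of the ants. With no raw depth in the table, a limit from depth cannot be given.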

Other observations

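Noon was also compared with the 8 am controls, a test added after the data were seen, because the 9 am libraries differ among themselves. SWEET9 fell to 2450 ± 96.8 from 174589 ± 43459 (log2 fold change -6.12 ± 0.72, adjusted p = 1.21e-05) and CWINV4 to 17032 ± 1126 from 85673 ± 15035, among 10 of 19 sucrose genes that fell and 3 that rose (10 and 3 adjusted over the list alone). LHY fell to 1044 ± 63.1 from 118171 ± 19186, among 3 of 7 morning clock genes that fell (3 adjusted over the list alone), and TOC1 rose to 4806 ± 233 from 942 ± 41.4, among 3 of 9 evening clock genes that rose and 3 that fell (5 and 3 adjusted over the list alone). GI averaged 10562 ± 1750 against 3926 ± 743 (adjusted p = 0.0916), and SPS1F fell to 3881 ± 124 from 6102 ± 389. The starch breakdown genes GWD1 and SEX4 rose, GWD1 to 3671 ± 174 from 810 ± 59.3, among 8 of 19 that rose and 3 that fell (9 and 4 adjusted over the list alone), and APS1 fell to 494 ± 19.3 from 3062 ± 398, among 6 of 16 starch synthesis genes that fell and 2 that rose (7 and 2 adjusted over the list alone). Photosynthesis genes fell in 24 of 33 cases (27 adjusted over the list alone), with LHCB5 at 399 ± 35.2 against 17970 ± 4309, and heat shock genes in 9 of 14 (9 adjusted over the list alone). LAC4, 1 of 12 xylem genes (1 adjusted over the list alone), HT1, 1 of 5 guard cell genes (2 up and 1 down adjusted over the list alone), and GL2, among 2 of 8 cuticle and epidermis genes (2 adjusted over the list alone), rose, GL2 to 1372 ± 93.6 from 412 ± 135. Of the remaining lists 6 of 16 jasmonate genes fell and 1 rose (6 and 1 adjusted over the list alone), 7 of 23 salicylate genes fell and 4 rose (7 and 4 adjusted over the list alone), and 4 of 18 cell cycle genes fell and 1 rose (4 and 1 adjusted over the list alone). Of the endoplasmic reticulum genes 5 of 9 fell (5 adjusted over the list alone), of the phenylpropanoid genes 3 of 21 (1 adjusted over the list alone), while 2 of 4 nectary development genes (2 adjusted over the list alone) and 1 of 5 phloem genes (1 adjusted over the list alone) rose, and no drought gene passed.

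In all, limma called 4585 genes at noon against 8 am, 2415 higher and 2170 lower. With both near-identical pairs, at noon and without ants, taken as 1 library each it called 3198. The count was 6994 in a fit of these groups alone, 7466 with array quality weights and 2436 at a change of at least 2-fold. The groups did not overlap in 65.7% of genes, where chance gives 10% if all libraries are independent. Noon samples 1 and 3 may not be, and for 2 libraries against 3 chance gives 20%. As lists, adjusted over these 18 alone, photosynthesis (adjusted p = 1.91e-10, and adjusted p = 0.167 with an estimated correlation) and heat shock (adjusted p = 0.000156, and adjusted p = 0.569 with an estimated correlation) were lower, as were the endoplasmic reticulum, morning clock and sucrose lists, at adjusted p = 0.623, 0.167 and 0.569 with an estimated correlation. The drought list had a median above 0 and a mean below 0, and the medians of the drought, xylem and cuticle lists went below 0 under median-of-ratios scaling.

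In the single 2 pm library LHY stood at 2475, SWEET9 at 22682, CWINV4 at 10697, PR1 at 3376 and BGL2 at 251. In the single library with returned ants these values were 142300, 200992, 6011, 860 and 1233. Against the mean of the 8 am controls the median of the xylem list in that library was -4.26 on the log2 scale, that of the phenylpropanoid list -1.18 and that of the photosynthesis list -1.19; in the 2 pm library these were 0.09, 0.69 and 0.53. All genes of the 2 pm library had a median of 0.49 above the controls. After median-of-ratios rescaling, which left 0.02 of this, its 3 list medians were -0.38, 0.21 and 0.05, while those of the library with returned ants (0.03 over all genes) were -4.27, -1.19 and -1.20. The 2 pm library listed 1 gene at 0, where the others listed 46 to 249.

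Sample 1 of each ant treatment deviated from its group in the same direction as sample 1 of the other treatments (correlations across genes of 0.36 to 0.54).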
